A study of Oryza sativa with 6 samples.

How the data were processed

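Messenger RNA was sequenced from nodal roots, S-type lateral roots and L-type lateral roots of rice (genotype label Mulai), each under control conditions and after 7 days in 50 mM NaCl. Each of the 6 groups holds 1 library, so no group has a replicate. Per the labels, the libraries were strand-specific and RNA was extracted with an RNeasy kit. The labels do not say whether the 3 root types came from the same plants, nor at what time of day roots were collected.

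The authors' processing notes name Trimmomatic 0.32, Bowtie, TopHat2 2.0.11, Cufflinks 2.2.1 and Cuffdiff 2.2.1 with the build IRGSP-1.0, without stating their settings. The deposited count table holds a scaled signal: fragment counts per gene multiplied by 1 factor per library. Between 99.8% and 99.96% of the values in a library were whole multiples of its step within a tolerance of 0.02 fragments. A fragment was worth 0.869, 1.286 and 1.25 in the control nodal, S-type and L-type libraries and 0.829, 0.900 and 0.920 in the salt libraries in the same order. The authors also deposited a table of FPKM values for all 15 pairs of libraries, with p-values and adjusted q-values from Cuffdiff and a yes or no call. The count table has 37942 gene models on 12 chromosomes, of which 37007 carry an identifier of the Rice Annotation Project.

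The files pair no identifier with a gene name. Gene symbols were recalled with their identifiers in lists written before the data were examined, and each was checked against a reference gene table of another rice assembly. A symbol was kept when the table placed it on the same chromosome, in the position expected from neighbouring list members, with a length of 0.4 to 1.6 times that of the gene model. An earlier fixed distance limit was replaced by this rule after it was seen which genes passed. Of 110 symbols in the lists, 77 passed, and of 51 symbols added after the values were seen, 34 passed. The lists cover sodium and potassium transport, the abscisic acid and dehydration response, root initiation and patterning, aquaporins, nitrogen, phosphate and iron uptake, the cell cycle, secondary wall cellulose synthases, root hairs and shoot photosynthesis. Lists of the iron deficiency response, the circadian clock, primary wall cellulose synthases, expansins, fermentation and named top-ranked genes were added afterwards. The 26 lists defined by gene descriptions could not be used, because the reference table gives no description. All coordinates are 1-based on IRGSP-1.0.

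The plan made before the data were examined was an edgeR test on estimated counts. Since the deposited values are a scaled signal, the test used instead was limma 3.58.1 with a trend, on log2 of the TMM-scaled value plus 1. The edgeR 4.0.16 quasi-likelihood test on recovered fragments became an alternative. The model was additive, with root type and treatment, and left 2 residual degrees of freedom. Its error is therefore how far the salt effect varies between root types, or the root type effect between treatments, and not a spread between replicates. After filterByExpr by treatment, 20136 genes were tested, and calls had a Benjamini-Hochberg adjusted p under 0.05. Gene lists with at least 3 tested members were compared with all other genes by camera, with a preset correlation of 0.01. Camera used the same log2 values as the limma test, where the plan had named log2 CPM with a prior count of 2. The p-values were adjusted over 7 lists, and over 4 lists for those added. Camera with an estimated correlation was run beside the preset one. The estimated version draws its p from the 2 residual degrees of freedom, and the preset version does not. A weaker p with it therefore need not reflect correlated genes. For the aquaporins and salt the estimated correlation was -0.0106, yet the unadjusted camera p rose from 0.000299 to 0.062. The test on simulated data with 2 residual degrees of freedom recovered 82% of genes given a 2-fold salt effect and 100% of those given a 4-fold effect, with 13 false calls among 19875 genes. For L-type against S-type roots it recovered 62% and 100%, with 16 false calls among 19919 genes. All simulated genes shared 1 dispersion of 0.027, and no gene had a spread of its own. The simulated effect was the same in every root type or treatment. The recovered shares may therefore be too high for the real libraries.

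Single pairs of libraries have no test. The log2 ratio of the deposited scaled values plus 1 was taken, and genes were counted with an absolute log2 ratio of at least 1 and at least 50 scaled fragments in the highest library. Exact conditional binomial 95% intervals of the ratio, and 100 simulations with Poisson error alone, cover counting error only. Fragments are not independent molecules. The median ratio of a list was placed among 10000 random lists of the same size matched on expression in 10 bins. Genes of a random list were drawn independently, while members of a real list may move together. The estimated correlation for salt was 0.871 for the secondary wall cellulose synthases and 0.543 for the dehydration list. An extreme percentile can therefore reflect a shared signal. The percentiles describe these libraries and are not tests. Differences of the salt response between root types are differences of these log2 ratios and have no residual degrees of freedom.

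Named genes followed a rule fixed before the data were examined: the 10 largest changes in each direction among salt calls and among L-type against S-type calls with the same direction in each root type or treatment and a mean of at least 50 fragments, the 5 largest in each direction of every single pair with at least 200 fragments, and list members reaching 50 fragments. Genes without a checked symbol are counted, with a few given by identifier.

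Alternatives included edgeR, DESeq2 1.42.0, log2 CPM, other scalings, filters and pseudocounts, a model without the block, and leaving out each root type. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.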

Results

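Under control, 7897875 fragments fell in genes of nodal, 6229661 of S-type and 5620282 of L-type roots. Under salt the totals were 7908373, 8711710 and 7194615. S-type laterals are the short roots that do not branch, and L-type laterals are longer and branch. With 1 library per group there were no replicates, and the intervals below cover counting error only. The first principal component carried 74.3% of the variance and the second 11%. Across genes, which are not independent replicates, the Spearman correlation was 0.792 between control nodal and control S-type roots. It was 0.909 between control nodal and control L-type roots and 0.908 between control S-type and control L-type roots. Between salt and control it was 0.979 in nodal, 0.978 in S-type and 0.966 in L-type roots.

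**Figure D1:**
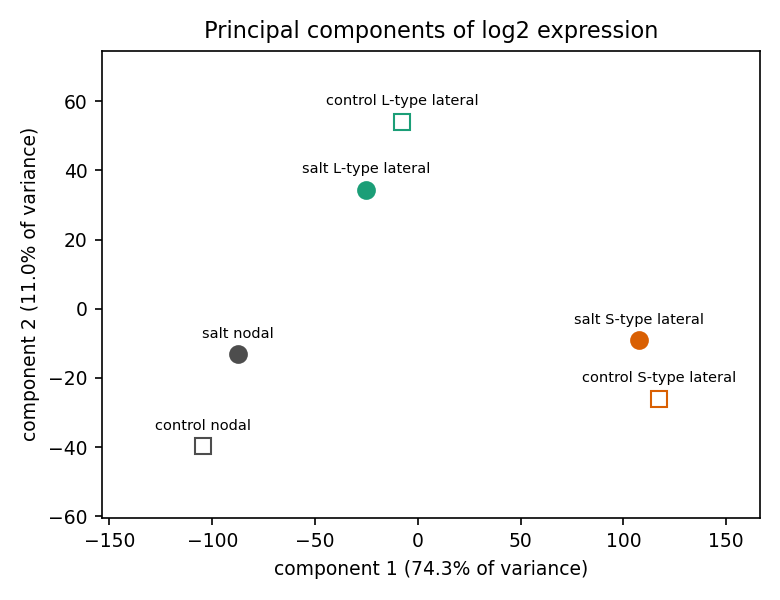
Principal components of the log2 scaled values of the 6 libraries, 1 point per library, with the share of variance on each axis. The 3 root types separate along the first component, which carries 74.3% of the variance.

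The first question is which genes respond to salt in every root type. YSL2 (Os02g0649900, chromosome 2, 26170850 to 26175202), a transporter of metal complexes with nicotianamine, fell by 5.36 on the log2 scale (SE 0.52, limma adjusted p = 0.0467), from 1801 to 26.1 scaled fragments in S-type, from 898 to 10.1 in L-type and from 74.7 to 4.98 in nodal roots. ZIP1 (Os01g0972200, chromosome 1, 42905570 to 42907462), of the zinc and iron transporter family, rose by 1.91 (SE 0.19, adjusted p = 0.0467). The clock gene LHY (Os08g0157600, chromosome 8, 3360788 to 3373437), which peaks around dawn in plants, fell by 2.61 (SE 0.20, adjusted p = 0.0291). The evening clock gene PCL1 (Os01g0971800, chromosome 1, 42874273 to 42875515) rose by 5.42 (SE 0.43, adjusted p = 0.0291). Its control libraries held 1 to 3 fragments, so the fitted change depends on the pseudocount, and the log2 ratio intervals were 3.23 to 7.13 in nodal, 3.89 to 11.71 in S-type and 4.64 to 12.44 in L-type roots. ZIP1, LHY and PCL1 received their names after their values were seen.

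In all, 24 of 20136 genes passed the threshold for salt, 13 higher and 11 lower, and all 24 moved the same way in the 3 root types. That is not separate evidence, since the model's error is how far the salt effect varies between root types. Among those without a name, Os01g0322700 rose by 6.03 and Os07g0531200 by 3.85, while Os08g0189600 fell by 2.63 and Os02g0606200 fell by 2.39. The fitted rises depend on the pseudocount, since Os01g0322700 held 6, 0 and 6 fragments in the control nodal, S-type and L-type libraries and Os07g0531200 held 3, 31 and 9. The number of calls depended on the method: it was 28 with edgeR, 170 with DESeq2, 2 with a mean of at least 50 fragments required and 0 in limma without the root type block, where 199 genes had an unadjusted p under 0.05. It was 3 without the nodal, 1 without the S-type and 45 without the L-type libraries.

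Several water channel genes had lower values under salt, and others did not. Of 13 tested aquaporins, 0 passed the threshold over all genes and 5 were lower adjusted over the list alone, with a median log2 change of -0.32 (camera adjusted p = 0.00209, and adjusted p = 0.434 with an estimated correlation). PIP2;3 had a log2 change of -1.30 (SE 0.20, adjusted p = 0.161), with ratios of -0.76 in nodal, -1.85 in S-type and -1.30 in L-type roots. PIP2;4 had -1.51 (SE 0.29, adjusted p = 0.230), PIP1;3 had -0.79, TIP2;1 had -0.65 and PIP2;1 had -0.46. The silicon channel Lsi1 had 0.39, TIP1;2 had 0.16 and TIP2;2 had 0.05, with ratios in nodal roots of 0.83, 0.77 and -0.55.

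The other fixed lists gave no call for salt. Among the 4 tested of 12 sodium and potassium genes, 0 passed over all genes and 1 was lower adjusted over the list alone: the potassium channel AKT1, with -1.01 (SE 0.19, adjusted p = 0.205). SOS1, NHX1, HAK5, CBL4 and HKT1;4 failed the check of names, so the list is silent on them. The list had a camera adjusted p of 0.766. Among 14 members of the abscisic acid and dehydration list 0 passed by either adjustment, and the list had a camera adjusted p of 0.777 (0.0254 without the L-type libraries). P5CS2, an enzyme of proline synthesis, had a log2 change of 1.90 (SE 0.44, adjusted p = 0.308). Of 10 genes of nitrogen, phosphate and iron uptake, YSL2 fell and 0 rose over all genes. Adjusted over the list alone the nitrate transporter NRT2.3 was also higher, with 1.11 (SE 0.23, adjusted p = 0.268 over all genes), and the list had a camera adjusted p of 0.777. None of 8 root initiation genes, 6 cell cycle genes or 3 secondary wall cellulose synthases passed by either adjustment, with camera adjusted p of 0.766, 0.789 and 0.777. Root hair and shoot photosynthesis lists had too few tested members for a list test. The root hair genes EXPA17 and CSLD1 had 0.78 and 0.40. CAB1R, a light-harvesting protein gene marking green tissue, had -1.72 (SE 0.21, adjusted p = 0.0828). It was lower adjusted over the list alone (limma adjusted p = 0.000149), where it was the only tested member, so that nothing was adjusted for. Its ratios were -2.01 (-2.61 to -1.52) in nodal, -1.34 (-2.11 to -0.67) in S-type and -1.80 (-2.28 to -1.38) in L-type roots. CAB2R, of the same list, had -2.43 (-3.24 to -1.81) in nodal roots, from 113 to 21 fragments, and at most 3 fragments in any lateral library.

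The lists added after the values were seen gave no call for salt by camera either. The adjusted p was 0.757 for 5 genes of the iron deficiency response, 0.573 for 8 clock genes, 0.998 for 5 primary wall cellulose synthases and 0.567 for 7 expansins. In the iron list 0 genes passed over all genes, and 2 were higher and 3 lower adjusted over the list alone. In the clock list LHY fell and PCL1 rose over all genes, and 3 were higher and 1 lower adjusted over the list alone, the others being PRR1 with 0.75 and GI with 0.67. The fermentation genes PDC2 and ADH1 had -0.05 and -0.05.

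The second question is how salt acted in each root type. In S-type roots, several genes of iron uptake were much lower under salt, though the lowest named ratio, -6.91, was that of Os01g0608101. NAS2 (Os03g0307200, chromosome 3, 10926323 to 10927978) and NAS1 (Os03g0307300, chromosome 3, 10929507 to 10930895), which make nicotianamine, had log2 ratios of -5.65 (interval -6.12 to -5.28) and -5.05 (-5.48 to -4.69). The metal transporter NRAMP1 (Os07g0258400, chromosome 7, 8965787 to 8970880) had -5.17, and NAAT1 (Os02g0306401, chromosome 2, 11997126 to 12002625), an enzyme of phytosiderophore synthesis, had -3.70. In S-type roots the whole list of nitrogen, phosphate and iron uptake had a median of 0.08 at percentile 80.45 of matched random lists, with 4 of 10 members at least 2-fold lower and 1 higher. In L-type roots NAS2, NAS1, NRAMP1 and NAAT1 had -3.68, -2.57, -3.93 and -2.49. In nodal roots they had 0.59 (0.44 to 0.74), 0.67 (0.50 to 0.85), -0.56 (-1.16 to -0.003) and -0.24 (-0.42 to -0.06). The iron phytosiderophore transporter YSL15 (Os02g0650300, chromosome 2, 26200020 to 26204980) had 1.58 in nodal, -2.22 in S-type and -1.23 in L-type roots. NAS3 was higher under salt in all 3 root types, with 0.96 in nodal, 1.59 in S-type and 1.04 in L-type roots. YSL16 had 1.48, 0.17 and 0.66, and IRO3 had -0.23, -0.59 and -1.36 in the same order. The iron deficiency list had a median of 0.36 at percentile 98.6 in nodal roots, over 4 members. IRO3 was left out there because it fell below the minimum of fragments. Over 5 members the list had -0.59 at percentile 0.185 in S-type and -1.36 at percentile 0.02 in L-type roots. The nodal and lateral medians therefore cover different members. With IRO3 added at a minimum of 10 fragments, the nodal median of the list reversed, as given below. This list, with NAAT1, NRAMP1, NAS3, YSL16 and IRO3, was chosen after the values were seen.

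**Figure D2:**
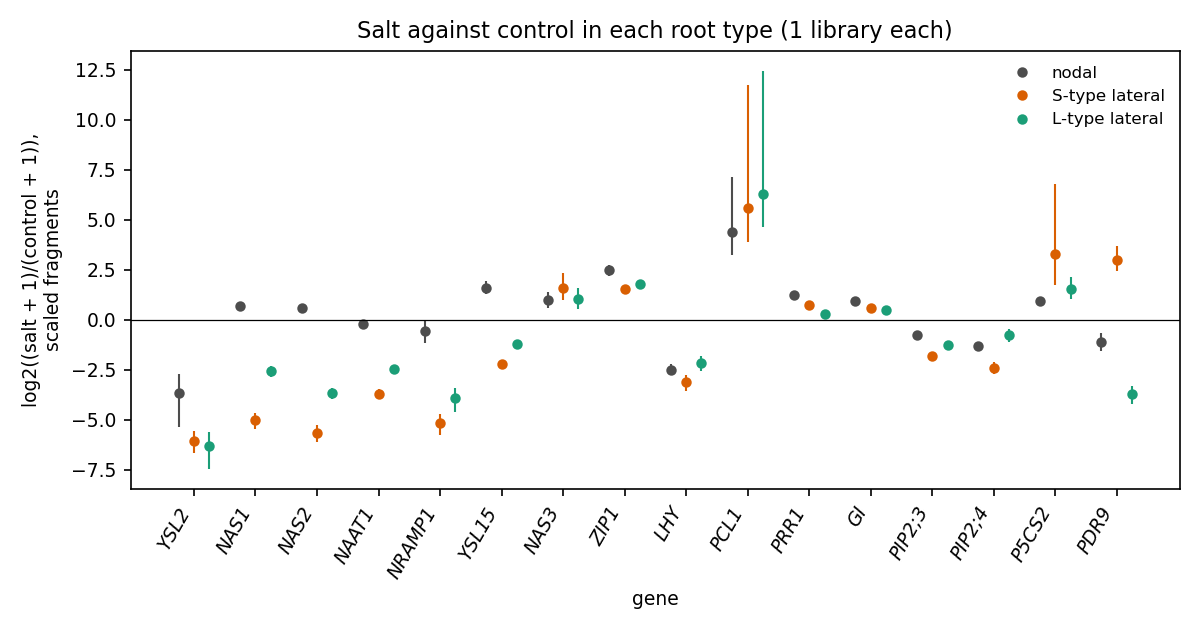
Log2 ratios of salt to control scaled values for 16 named genes in the 3 root types, with lines for the exact 95% counting interval. NAS2 lies at 0.59 in nodal, -5.65 in S-type and -3.68 in L-type roots.

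In nodal roots 193 genes were at least 2-fold higher and 266 lower under salt, against at most 4 from counting error in 100 simulations. The sodium transporter HKT1;5 had a log2 ratio of -1.47 (-2.28 to -0.81) in nodal roots, 0.51 (-0.32 to 1.43) in S-type and 0.37 (-0.61 to 1.45) in L-type roots. AKT1 had -1.51 in nodal, -0.98 in S-type and -0.53 in L-type roots. The median of the sodium and potassium list in nodal roots was -1.05 at percentile 0.02 of matched random lists, which is the ratio of HKT2;1 itself, while HAK1 had 0.02 and CIPK24 had 0.25. In S-type roots the median was -0.06 at percentile 39.3 and in L-type roots 0.08 at percentile 71.3, each over 3 members. The aquaporin median was -0.30 at percentile 0.03 and the dehydration list median 0.29 at percentile 99.95, with all 13 dehydration members within 2-fold. The laccase gene LAC3 had -2.16, and it was named after its value was seen.

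In S-type roots 240 genes were higher and 266 lower, against at most 9 from counting error. P5CS2 had a ratio of 3.26 in S-type roots, with an interval of 1.74 to 6.79 because its control library held 2 fragments, 0.90 in nodal and 1.54 in L-type roots. The aquaporin median was -0.46, below all of the 10000 random lists. In L-type roots it was -0.23 at percentile 7.61. The ABC transporter gene PDR9 (Os01g0609300, chromosome 1, 24075070 to 24081885) had 2.99 (2.44 to 3.68) in S-type, -1.11 (-1.58 to -0.68) in nodal and -3.74 (-4.23 to -3.35) in L-type roots, and it was named after its values were seen.

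In L-type roots 251 genes were higher and 646 lower, against at most 10 from counting error. The stress transcription factors NAC6 and DREB1C had ratios of -1.05 (-1.16 to -0.93) and -1.36 (-1.61 to -1.12) there, against 0.28 and 0.07 in nodal roots. Of the 11 dehydration genes measured there, 1 was at least 2-fold higher, 2 lower and 8 within 2-fold, with a median of -0.15 at percentile 15.3. The list of nitrogen, phosphate and iron uptake had a median of -0.45 at percentile 0.24. The secondary wall cellulose synthases had a median of 0.58 at percentile 99.85, against -0.42 at percentile 0.72 in nodal roots. The ammonium transporter AMT1;1 had 1.30. Across genes the salt L-type library had a Spearman correlation of 0.923 with control nodal roots, against 0.909 for the control L-type library. The salt S-type library had 0.798, against 0.792 for the control S-type library.

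The responses overlapped more than independent lists would. The expected counts take every gene as equally likely to pass, although genes with more variable values pass more often in any pair. All salt libraries may also share a difference from control other than salt. The excess therefore need not be a shared response to salt. Nodal and S-type roots shared 40 higher genes (1.8 expected) and 35 lower genes (1.2 expected), nodal and L-type roots 48 (2.5) and 58 (4.2), and S-type and L-type roots 51 (2.2) and 75 (7.4). In all 3 root types 25 genes were higher and 23 lower, with 0.018 and 0.031 expected. Another 29 genes were higher in S-type and lower in L-type roots (7.4 expected), and 0 were lower in S-type and higher in L-type roots (2.2 expected). Against nodal roots, 5 genes were higher in nodal and lower in S-type roots (1.8 expected) and 3 the reverse (1.2), and 7 higher in nodal and lower in L-type roots (5.6) and 4 the reverse (1.9). Across genes the Pearson correlation of the log2 ratios was 0.301 for nodal and S-type, 0.358 for nodal and L-type and 0.297 for S-type and L-type roots, and the Spearman correlation was 0.187, 0.256 and 0.170.

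The series asks for genes of lateral root development under salt, so the salt responses were set against each other. NAS1, NAS2 and NRAMP1 were among the largest negative differences of S-type from nodal roots. PDR9 was among the largest differences of L-type from S-type roots, and LAC3 among the largest positive differences of L-type from nodal roots. By at least 2-fold, 542 genes had a higher and 1005 a lower response in L-type than in S-type roots, where counting error gave at most 177. L-type against nodal roots had 531 higher and 781 lower (at most 123), and S-type against nodal roots 695 higher and 652 lower (at most 269). None of these differences could be tested. The dehydration list had a median difference of -0.39 at percentile 0.70 for L-type minus S-type, and the aquaporins -0.29 at percentile 0.21 for S-type minus nodal roots. The secondary wall cellulose synthases had 1.13 for L-type minus nodal roots, above all of the random lists, though these 3 genes may move together (estimated correlation 0.871). These genes are far higher in nodal than in S-type roots. If L-type libraries were mixtures, 145 genes high in nodal roots gave a median nodal share of 17.0% under control and 32.5% under salt. By 207 genes high in S-type roots it was 81.8% and 88.4%, so no single mixture accounts for both sets. This concerns L-type roots as a pure blend of nodal and S-type RNA. It does not exclude added nodal RNA in the salt L-type library, which stays open below, and both shares were higher under salt.

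The third question is how the root types differ. Genes of dividing cells were lower in S-type than in the other roots: all 6 cell cycle genes were higher in L-type than S-type roots over all genes and adjusted over the list alone, with a median of 1.47 (camera adjusted p = 0.000128, and adjusted p = 0.376 with an estimated correlation). CYCB1;1, a mitotic cyclin, was higher by 1.52 (SE 0.16, adjusted p = 0.00235). All 3 secondary wall cellulose synthases were higher in L-type than S-type roots by both adjustments, with a median of 2.85 (camera adjusted p = 0.00419, and adjusted p = 0.467 with an estimated correlation), and CESA4 (Os01g0750300, chromosome 1, 31422946 to 31428670) held 2281 scaled fragments in control nodal, 317 in control L-type and 46.3 in control S-type roots. The auxin transporter genes PIN1b and PIN2 were higher in L-type roots by 1.80 and 1.51, and the auxin response gene IAA11 by 1.21. Of the 8 root initiation genes 5 were higher and 1 lower by both adjustments (camera adjusted p = 0.141).

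Between L-type and S-type roots 6860 genes passed the threshold, 3808 higher and 3052 lower in L-type. The catalase gene CATA (Os02g0115700, chromosome 2, 825041 to 827640) was higher by 5.996 (SE 0.44, adjusted p = 0.00197), with 3797 scaled fragments in control nodal, 233 in control L-type and 1.286 in control S-type roots. The glucanase gene GLU5 was higher by 5.45 (SE 0.44, adjusted p = 0.00197). Both rest on 1 to 4 fragments in S-type roots, so the fitted values depend on the pseudocount, and both were named after their values were seen. Os11g0428800 held 67555 scaled fragments in control S-type and 1667 in control L-type roots, and Os02g0583700 held 39834 and 777. Of 13 aquaporins 6 were higher and 3 lower (camera adjusted p = 0.317), and of 14 dehydration genes 2 were higher and 6 lower (camera adjusted p = 0.141), by both adjustments. Of 10 uptake genes 1 was higher and 2 lower (camera adjusted p = 0.293), and of 4 sodium and potassium genes 0 were higher and 1 lower (camera adjusted p = 0.293), by both adjustments.

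**Figure D3:**
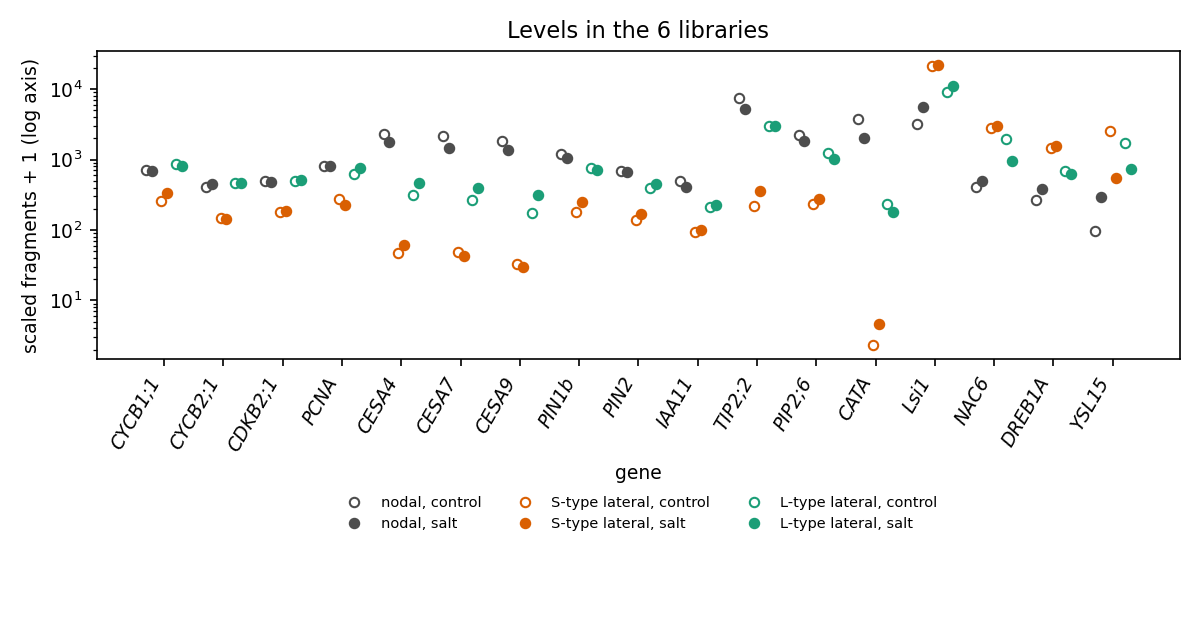
Scaled fragments plus 1 on a log axis for 17 named genes in the 6 libraries, open symbols for control and filled for salt. CESA4 lies at 2281 in control nodal and 46.3 in control S-type roots.

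S-type and nodal roots differed most. The 6 cell cycle genes were lower in S-type roots, with a median of -1.38 (camera adjusted p = 0.00265, and adjusted p = 0.363 with an estimated correlation), as were the 3 secondary wall cellulose synthases, with a median of -5.30 (camera adjusted p = 0.00431, and adjusted p = 0.363 with an estimated correlation), in each case over all genes and adjusted over the list alone. Of 13 aquaporins 2 were higher and 7 lower, and 8 lower adjusted over the list alone (camera adjusted p = 0.0290, and adjusted p = 0.363 with an estimated correlation). TIP2;2 had -4.49, whereas the silicon channel Lsi1 had 2.35. Of 14 dehydration genes 8 were higher and 2 lower, of 10 uptake genes 6 were higher and 1 lower, of 8 root initiation genes 2 were higher and 5 lower, and of 4 sodium and potassium genes 2 were higher and 0 lower, by both adjustments, with camera adjusted p of 0.0597, 0.133, 0.0597 and 0.185. In all, 11089 genes passed the threshold, 5433 higher and 5656 lower in S-type roots.

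L-type and nodal roots differed less. The 3 secondary wall cellulose synthases were lower in L-type roots by both adjustments, with a median of -2.45 (camera adjusted p = 0.000244, and adjusted p = 0.358 with an estimated correlation). Of 13 aquaporins 1 was higher and 5 lower, and 10 lower adjusted over the list alone, with a median of -0.72 (camera adjusted p = 0.000223, and adjusted p = 0.335 with an estimated correlation). None of the 6 cell cycle genes passed by either adjustment (camera adjusted p = 0.770). Of 8 root initiation genes 3 were lower over all genes, and 1 was higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0817). Of 14 dehydration genes 2 were higher and 2 lower, and 7 higher adjusted over the list alone (camera adjusted p = 0.131). Of 4 sodium and potassium genes 2 were higher by both adjustments (camera adjusted p = 0.140), and of 10 uptake genes 0 passed by either (camera adjusted p = 0.120). In all, 2387 genes passed the threshold, 1374 higher and 1013 lower in L-type roots.

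Under control conditions alone, without a test, 2008 genes were at least 2-fold higher and 1799 lower in L-type than S-type roots, 1757 higher and 1265 lower in L-type than nodal roots, and 3447 higher and 3317 lower in S-type than nodal roots. Counting error alone gave at most 33, 9 and 24 genes.

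The authors' own Cuffdiff calls, from their deposited table, numbered 0 for salt in nodal, 14 in S-type and 5 in L-type roots. The 14 include NAS1, NAS2, NAAT1 and the iron transporter gene IRT2. Under control they numbered 233 between S-type and nodal, 39 between nodal and L-type and 28 between S-type and L-type roots.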

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

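All tests of explanations in this part were chosen after the results were seen.

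The salt responses of YSL15 and PDR9 pointed in opposite directions in different root types, with counting intervals that exclude 0. For YSL15 the log2 ratio in S-type roots minus that in nodal roots was -3.81, and in L-type minus nodal roots -2.82. For PDR9 it was 4.10 in S-type minus nodal roots and -6.74 in L-type minus S-type roots. These differences between root types were not tested, since each group holds 1 library.

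The genes NAS1, NAS2, NAAT1 and NRAMP1 were much lower under salt in both lateral root types and slightly lower or higher in nodal roots, and were picked because they show this. NRAMP1 went from 55.6 to 37.3 scaled fragments in nodal, from 1138 to 30.6 in S-type and from 392 to 24.8 in L-type roots. Its nodal control level was thus already near the lateral levels under salt. NAS1 and NAS2 rose in nodal roots, from 370 to 590 and from 535 to 804. Too few fragments in nodal roots is argued against for these genes only, since 4 of 4 have a nodal counting interval wholly above both lateral intervals. The choice of genes made such a count likely. Among other iron genes YSL15 showed the same split, while YSL2 also fell in nodal roots (-3.66) and NAS3 was higher under salt in all 3 root types. The smallest nodal minus lateral difference over the 4 genes and both lateral types was 2.24 (log2) with 3 scalings, which differ too little to decide anything. Unscaled fragments, added after that value was seen, cannot decide on scaling of the libraries either. The factor of a library is the same for all its genes, so leaving it out shifts their ratios nearly alike. For the median gene the difference moved by 0.44 for S-type and 0.37 for L-type roots. The smallest difference of the 4 genes was then 1.87, which these shifts nearly fixed beforehand. It shows only that the difference remains in unscaled fragments, and no conclusion on scaling as a cause is drawn. A response to salt that differs between root types, and a difference between single plants or pots, may each account for the pattern, and neither was tested. A different time of collection, taken up below for the clock genes, was not tested for these genes either.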

How the results depend on the processing

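The edgeR test on recovered fragments, the list test of unchecked symbols and of root types, and the added lists were chosen after the data were seen. Of 80 alternative values of the comparisons, 62 stayed within 1.5 times the main count and 18 moved. The 24 salt calls became 170 with DESeq2, 2 with a mean of at least 50 fragments, which all 24 had, and 0 without the root type block; the cause was not tested. Leaving out a root type gave 1 to 45 calls. With a minimum of 200 fragments, which leaves fewer genes, the counts for salt fell to 154 in nodal, 208 in S-type and 451 in L-type roots, and for control to 1917 (L-type and S-type), 1672 (L-type and nodal) and 3963 (S-type and nodal). The differences of the salt response fell to 695 (L-type and S-type), 582 (L-type and nodal) and 483 (S-type and nodal), the last to 874 with a pseudocount of 10. The list call for salt became 0 with an estimated correlation and 2 without the L-type libraries. In nodal roots the median of the iron deficiency list reversed, from percentile 98.6 to 7.33 with a minimum of 10 fragments, which adds IRO3 (-0.23) to the 4 members. For the 20 named salt genes, 143 of 220 alternative values kept their call and 77 lost it, with 0 reversed. The genes named for L-type against S-type roots were not followed in this way. Of 156 named ratios 150 stayed within their interval. The real split of the libraries gave 24 calls and the highest of the other splits 0; with 10 splits, of which 1 reached the real count, a share under 0.05 is out of reach. No paired analysis was possible because the groups share only replicate number 1; the root type block in the model is a factor of the design, not a replicate number. Depth limits genes near 3 fragments, which is 2.49 to 3.86 in scaled values.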

Other observations

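The lists of expansins, primary wall cellulose synthases and fermentation genes, and all tests of explanations in this part, were chosen after the results were seen.

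Genes of growing cell walls followed the root types. Of 7 expansins, which loosen walls, 5 were higher in L-type than S-type roots and 6 adjusted over the list alone (camera adjusted p = 0.00407, and adjusted p = 0.472 with an estimated correlation). In S-type against nodal roots 6 were lower by both adjustments (camera adjusted p = 0.00222, and adjusted p = 0.431 with an estimated correlation), and in L-type against nodal roots 4 were lower and 5 adjusted over the list alone (camera adjusted p = 0.00428, and adjusted p = 0.445 with an estimated correlation). Of 5 primary wall cellulose synthases 4 were higher in L-type than S-type roots (camera adjusted p = 0.0177, and adjusted p = 0.472 with an estimated correlation) and 5 lower in S-type than nodal roots (camera adjusted p = 0.00667, and adjusted p = 0.431 with an estimated correlation), by both adjustments. In L-type against nodal roots 1 was lower and 3 adjusted over the list alone (camera adjusted p = 0.00563, and adjusted p = 0.445 with an estimated correlation). The alcohol dehydrogenase gene ADH1 was higher in L-type than S-type roots by 3.41 and fell by 5.66 from nodal to S-type roots, values that depend on the pseudocount because the S-type libraries held 3 and 9 fragments. The other fermentation gene, PDC2, had -0.37 for L-type minus S-type roots (adjusted p = 0.0598, and 0.0221 adjusted over the list alone) and -0.24 for S-type minus nodal roots (adjusted p = 0.132). Both genes were lower in L-type than nodal roots, PDC2 with -0.61 (adjusted p = 0.0334) and ADH1 with -2.26 (adjusted p = 0.0293).

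L-type roots lay mostly between the others among genes chosen to differ strongly between nodal and S-type roots. The choice asked for an absolute log2 ratio of at least 3 under both treatments. If each L-type library were a mixture, 145 genes high in nodal roots gave a median nodal share of 17.0% under control and 32.5% under salt, and 207 genes high in S-type roots gave 81.8% and 88.4%. The quartiles under control were 8.5% to 28.6% and 67.0% to 90.1%, so no single mixture accounts for both sets. Under both treatments 25 genes were higher and 14 lower in L-type roots than in both other types, against 0 in each of 100 simulations of counting error.

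The dawn gene LHY was lower and the evening gene PCL1 higher under salt in all 3 root types. A candidate explanation is that salt and control roots were collected at different times of day: the evening genes PRR1 and GI were above control with intervals above 0 in 6 of 6 ratios. Other clock genes were lower in some or all root types: PRR73 had -0.09, -0.37 and -0.27 in nodal, S-type and L-type roots, PRR37 had -0.66 in L-type roots, and PRR95 had -0.45 there but 0.50 in nodal and 0.44 in S-type roots. The list median was 0.33 at percentile 99.8 in nodal, 0.16 at percentile 92.2 in S-type and 0.01 at percentile 59.7 in L-type roots. That salt acted on the clock predicts the same values and cannot be told apart from it, since 0 of 6 libraries have a time of day in their labels. A different collection time, if there was one, would bear on every comparison of salt with control here, and not on clock genes alone.

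The salt L-type library lay nearer to the nodal libraries than the control L-type library did, and S-type roots shifted the same way by less, from 0.792 to 0.798 with control nodal and from 0.818 to 0.833 with salt nodal roots (Spearman correlation across genes). Deeper sequencing is argued against: with all libraries thinned to the smallest total, the smaller gain in Spearman correlation across genes was 0.0134, against 0.0142 before thinning. Nodal root RNA in that library could account for it and stays open: a nodal share of 14.2% would be needed, and 2 of 23 genes far higher in nodal roots allow less than 4.73%, where at least 3 had been asked for. With the bound loosened to the whole needed share, a change tried after that result was seen, 8 of 23 genes fell under it, so the verdict hangs on the bound and no decision is drawn. The 34 genes far higher in S-type roots had a median log2 ratio of -0.80, lower than the -0.22 that dilution at the needed share alone would give, and a change of L-type roots under salt was not tested.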
